A study of Mus musculus with 30 samples.

How the data were processed

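RNA came from CD11c-selected bone marrow-derived dendritic cells in 6 groups of 5 biological replicates. Groups and replicate numbers came from the sample labels. Subpopulations with low and high MHC class II, named in the series title but in no sample label, were not compared. Whether a replicate is a mouse or a culture is not given in the sources used here, so p-values measure the spread between these samples. RNA was extracted with a column kit that removes genomic DNA, copied into labelled cRNA, and 750 ng of it was hybridised, per the labels' protocols. The sample carried Cy5 and the universal mouse reference RNA carried Cy3 on every array, per the labels, so no dye was swapped.

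Each array had 1 scanner file with spot intensity values, the median Cy5 and Cy3 brightness and local background, deposited as scanned and made with Feature Extraction 10.7.3.1 per the file headers. The same files hold a log10 ratio of Cy5 over Cy3, background subtracted and dye normalised by that software per the file headers. A table of the whole series holds 1 log2 ratio per probe and array, deposited by the authors after a limma step that the submitters' processing notes name without a version. Its scale, direction and centring were found by setting each column against log2 Cy5 over Cy3 of its own array after the steps described next: the correlation across probes was 0.999885 to 0.999998, and the column medians were 0.00584 to 0.0183, so its values are uncentred log2 ratios of sample over reference. 

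Intensities were background corrected with normexp (offset 50) and log2 ratios normalised by loess within each array in limma 3.58.1 under R 4.3.3. Local backgrounds that the scanner software marked as non-uniform were first set to the array's median background. The 1639 control spots had weight 0 in the loess fit and were then left out, as were spots marked as non-uniform or as population outliers on the array concerned, and spots of 1 probe were averaged. The number of probes saturated in Cy5 was 0. Of 41174 probes 22951 were named, through the transcript accession in the scanner files and a RefSeq table of 49997 genes, and 18223 stayed unnamed here. These covered 16358 genes, and 11256 remained after a filter that kept probes well above background in Cy5 on all 5 arrays of at least 1 group. Each gene was represented by its probe with the highest mean Cy5 signal, and 25 genes lacked a spot on some array (list tests took the group's mean there). The array design and the reference table use different genome builds, so no coordinates are given. The replicate arrays of a group were compared before averaging: over 60 pairs the SD of their differences was at least 3.08 times that of repeated spots, so no array was taken for a second scan of another, and that they are separate samples rests on the labels.

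The tests and lists were fixed before the data were examined. One mean per group was fitted with limma to all 30 arrays, which left 24 residual degrees of freedom, with empirical Bayes variances without a trend. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over genes within a comparison), and the number with at least a 2-fold change is given beside it. There were 11 comparisons: KO against control in each treatment, LPS at 6 and 24 h against unstimulated cells and against each other within each genotype, and the difference of log2 LPS responses, KO minus control, at each time.

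There were 26 gene lists. The sex-linked list had 0 members past the filter, and the other 25 covered MHC class I and II presentation, proinflammatory cytokines and chemokines, interferon-stimulated genes, maturation and migration, feedback inhibitors, pattern recognition, the IRF family, dendritic cell identity, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, lipid efflux, lysosome, immediate-early and heat shock genes, arginine and alternative activation, and markers of macrophages, neutrophils, plasmacytoid dendritic cells, B cells, T and NK cells, mast cells with basophils and eosinophils, erythroid cells with megakaryocytes, and stroma with endothelium. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 275 tests, of which 94 were called. With an estimated correlation 0 of 275 were called, fry, which asks whether a list moves on balance in 1 direction without comparing it with other genes, called 49, and its mixed form, which asks for change in either direction, 107. List counts adjust each member over all genes, and beside this over the list alone, which gave the same count where it is not stated.

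The genes named in each main comparison were the 8 with the largest rise and the 8 with the largest fall among called genes whose 5 arrays of 1 group all lay beyond those of the other (for differences of responses the call alone), up to 3 members per described list in the direction most called members took and 1 in the other, passing over probe and accession names, and a fixed set of dendritic cell and cytokine genes that includes Irf4, Il6, Tnf, Cxcl10, Cd74 and Cd86. Some genes that the rule chose are not reported here, and counts of named genes include them. Of the fixed set, Il12b and Cd40 had no named probe, and Il10 did not pass the filter. A gene not well above background on any array of 1 group has only a bound there. That bound is the mean normalised log2 Cy5 signal of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background, after loess and Aquantile, and it is open to dye bias. Well above background on only some of 5 arrays were Csf2 (1, control 6 h), Btbd17 (1, control 24 h), Cxcl10 (2, unstimulated control), Ccr2 (2, KO 24 h) and other named genes with 3 or 4, such as Upb1 (3, unstimulated KO).

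The same fits were tested on simulated data of 11256 genes with 200 changed, 100 at each of 2 sizes. Over 11 comparisons they recovered 51 to 75% of log2 changes of 1 and 79 to 98% of those of 2. At most 6.86% of calls were unchanged genes. Rates may differ on the arrays, where 1 component held 52.9% of within-group variance. Whether the replicate numbers pair the arrays was decided from the correlation of deviations from group means before calls were compared. All 5 pairs were above 0.1 for control LPS 24 h against unstimulated (0.177 to 0.732), KO LPS 6 h against unstimulated (0.109 to 0.657) and KO LPS 24 h against 6 h (0.792 to 0.875), where a fit with the number as a block is given beside the result, and not for the other 8 comparisons. The alternatives tried were no background subtraction (on median, not mean, signals), Agilent's log ratio, median centring, Aquantile between arrays, the deposited table, Cy5 alone with quantile normalisation, no signal filter or a filter over all 30 arrays, the mean of a gene's probes, only the compared groups' arrays, the replicate number or the slide as a block, a trended robust variance, array weights, the other list tests, and each array left out in turn. Slide and scan day came from the scanner files, and 9 alternatives were added after the data were seen. Plots used matplotlib 3.10.9.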

Results

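Gene expression was measured in bone marrow-derived dendritic cells, antigen-presenting cells grown in culture from mouse bone marrow, after selection with CD11c beads. The donors were C57BL/6 mice that carried a CD11c-Cre transgene either alone (control) or with loxP-flanked alleles of Irf4 (Irf4 knockout, KO). Irf4 encodes a transcription factor of the interferon regulatory factor family. The Cre recombinase under the CD11c promoter deletes the flanked sequence in CD11c-expressing cells. Cells of each genotype were unstimulated or had received lipopolysaccharide (LPS), the bacterial ligand of the Toll-like receptor TLR4, for 6 or 24 h. This gave 6 groups of 5 biological replicates. Each of the 30 arrays set sample RNA against a universal mouse reference. A level is a log2 ratio to that reference, which cancels between groups. The median Cy5 signal per array was 101 to 151, and 18465 to 27230 of 41174 probes (44.8 to 66.1%) were well above background. Of the genes with a named probe, 11256 entered the tests, and the 5 arrays per group limit the precision.

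Irf4 was lower in KO than in control cells under each treatment. Its mean log2 ratio in unstimulated cells was 1.41 ± 0.24 in control and -1.49 ± 0.80 in KO arrays (SD, n = 5 each), 7.48-fold apart. After 6 h of LPS it was 2.31 ± 0.24 in control and -0.11 ± 0.30 in KO arrays (5.34-fold), and after 24 h 2.14 ± 0.33 and -0.0303 ± 0.44 (4.50-fold, n = 5 each). All 5 KO arrays lay below all 5 control arrays in each treatment (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 arrays can give). The gene was measured by 1 probe, whose place relative to the deleted part is not given in the sources used here. It was well above background on every array but KO unstimulated replicate 5. With the slide as a block the KO differences were -2.18, -1.96 and -2.42 at 0, 6 and 24 h, and the call at 6 h was lost (adjusted p = 0.0907).

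**Figure D1:**
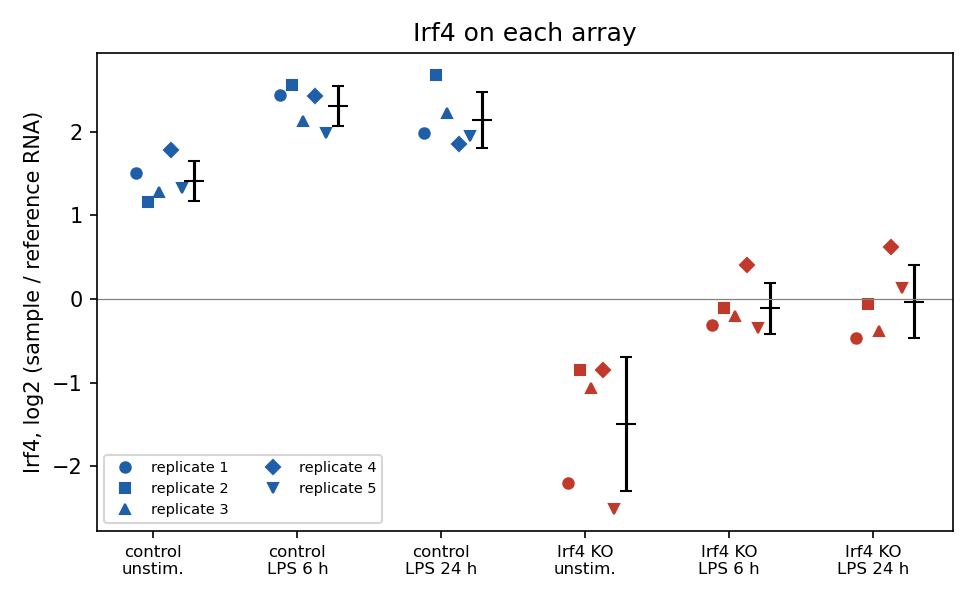
Irf4 log2 ratio to the universal reference (vertical axis) on each of the 30 arrays, by genotype and treatment (horizontal axis) with 1 marker shape per replicate number; bars give the mean ± SD of 5 arrays. The KO arrays lie between -2.51 and 0.619, and the control arrays between 1.16 and 2.68.

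3 features of the sample set bear on every comparison. The arrays labelled control LPS 6 h replicate 3 and control LPS 24 h replicate 2, which shared a slide scanned on a later day, each lay nearest an unstimulated control array. Across 1098 genes that LPS changed at least 2-fold in KO cells at 6 h, the first had a slope of -0.0310 on the KO response, against 0.660 to 0.872 for the other 4 arrays of its group. Across 728 such genes at 24 h, the second had a slope of 0.105, against 0.598 to 0.823 for the other 4. The mean of replicates 4 and 5 differed from that of replicates 1 to 3 in a like direction in all 6 groups for 6169 of 11256 genes (54.8%, against 3.13% for independent signs). In unstimulated KO cells, however, replicate 4 lay with replicates 2 and 3, and replicates 1 and 5 stood apart from these. The arrays lay on 9 slides, none of which held both genotypes at 1 treatment. A KO difference with the slide as a block is therefore summed over a chain of slides that 1 or 2 arrays link. With a term for replicates 1 to 3 against 4 and 5 as well, 226, 11 and 548 genes were called for KO against control at 0, 6 and 24 h.

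In control cells at 6 h of LPS, the interferon-induced chemokine Cxcl10 rose 175-fold (log2 difference 7.45, SE 1.21, adjusted p = 0.000462, n = 5 each). The chemokine Cxcl3 rose 17.0-fold (4.08 ± 0.65 on the log2 scale, ± SE). The GTPase Iigp1 (4.26 ± 0.80), Cmpk2 (4.13 ± 0.75), the pentraxin Ptx3 (3.94 ± 0.72), the histamine-forming enzyme Hdc (3.82 ± 0.59), the cytokine Il1a (3.58 ± 0.60) and Inhba (3.07 ± 0.63) rose as well. Falls were of the receptor Cd244a (-2.29 ± 0.44), Galnt14 (-2.05 ± 0.42) and the SLAM adaptor Sh2d1b1 (-1.96 ± 0.51). Susd3 (-1.91 ± 0.45), Cxcr4 (-1.85 ± 0.33) and Rgs18 (-1.59 ± 0.31) fell as well.

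Of the 22 measured proinflammatory cytokines and chemokines 21 rose, among them Edn1 (3.69 ± 0.59), Tnf (3.34 ± 0.54), Il6 (4.17 ± 1.04) and Il1b (4.03 ± 0.91). The list as a whole rose (adjusted p = 7.63e-18, 0.495 with an estimated correlation). Interferon-stimulated genes rose in 35 of 37 cases (37 adjusted over the list alone, adjusted p = 1.74e-28, 0.495 with an estimated correlation). The antiviral regulator Irf7 rose by 3.41 ± 0.80. The chemokine Cxcl9 and interferon beta (Ifnb1), which were not well above background in unstimulated cells, rose at least 2.84-fold and at least 3.47-fold. The feedback inhibitors had 10 members up and 1 down of 23 (17 up and 1 down adjusted over the list alone), and the list rose (adjusted p = 2.11e-08, 0.557 with an estimated correlation). Among them were the receptor antagonist Il1rn (1.81 ± 0.30), the NF-kB inhibitor Nfkbie (1.15 ± 0.21) and the RNase Zc3h12a (2.37 ± 0.43) up and Sigirr (-1.40 ± 0.32) down. In the pattern recognition list 7 rose and 1 fell of 25 (12 and 2 adjusted over the list alone), and the list rose (adjusted p = 0.00145, 0.743 with an estimated correlation). Tlr2 (2.00 ± 0.32), the TLR4 co-receptor Ly96 (0.74 ± 0.16) and the scavenger receptor Marco (2.94 ± 0.43) rose, and Tlr4 fell (-1.01 ± 0.25).

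Maturation and migration genes rose in 7 of 30 cases (10 adjusted over the list alone, adjusted p = 0.00136, adjusted p = 0.785 with an estimated correlation), with Il15ra (1.63 ± 0.32), the survival factor Birc3 (1.00 ± 0.22) and the costimulatory ligand Cd80 (1.39 ± 0.35) among them. None of the 19 measured MHC class II presentation genes was called by limma (0 up and 1 down at an unadjusted p under 0.05, adjusted p of the list = 0.308). H2-Ab1 (0.00946 ± 0.12) and Cd74 (0.0704 ± 0.35) differed by less than their error. MHC class I presentation had 3 of 18 members up (adjusted p = 0.00772) and the IRF family 6 of 23 (adjusted p = 0.0392). Both lists had adjusted p = 0.785 with an estimated correlation, and Irf4 was among the latter (0.90 ± 0.27, adjusted p = 0.0272). Oxidative phosphorylation, with 1 member up and 2 down of 35, fell (adjusted p = 0.0316, adjusted p = 0.785 with an estimated correlation). Of the dendritic cell identity genes, the transcription factor Zbtb46 rose by 1.02 ± 0.24 and Cd24a fell (-1.69 ± 0.33).

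In all 1314 genes were called, 806 up and 508 down, and 522 changed at least 2-fold (limma, adjusted over 11256 genes). Of 35 named genes called, 27 had all 5 LPS arrays on the called side of the unstimulated mean (by rule for the largest), and Il6, Ifnb1, Irf7, Il15ra, Birc3, Ly96, Zbtb46 and Cd24a had 4. Of the 8 list calls 3 had all 5 and the other 5 had 4. Without the 2 arrays of the later slide 2880 genes were called and all 35 named genes kept the call, 12 with rises over 1.5 times as large, such as Il6 (5.81) and Cxcl10 (9.13, but 6.69 and 6.62 without LPS replicate 1 or 2). With the slide as a block 3873 genes were called and 33 of the 35 kept the call (Cd80 and Irf4 lost it). On the slide with both groups, 1288 of the 1314 genes (98.0%) had the called direction. Its arrays (LPS replicates 1 and 2, unstimulated 4 and 5) also made the calls, and LPS is not separated from replicate number there. The 10 compared arrays alone gave 75 genes and 14 of the 35, and leaving out LPS replicates 1, 2 or 3 gave 744, 747 or 2599 genes. Sh2d1b1 lost its call without LPS replicate 1 or 2, and Irf4 without any of 5 arrays (unstimulated replicates 2 and 3, LPS replicates 1, 2 and 4). Irf4, Rgs18, Sh2d1b1 and oxidative phosphorylation were not called with Agilent's own log ratios or with backgrounds as scanned, nor were Irf4 and oxidative phosphorylation with median centring. The IRF and oxidative phosphorylation calls also ended without unstimulated replicate 4 or 5 or LPS replicate 1 or 2 (for oxidative phosphorylation LPS replicate 5 as well). The split of calls moved to 698 up and 742 down with Agilent's log ratios, 496 and 165 with median centring, and 640 and 735 with Cy5 alone.

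After 24 h of LPS, Cxcl3 rose in control cells 20.1-fold (log2 difference 4.33, SE 0.65, adjusted p = 0.000116, n = 5 each), Cxcl10 18.9-fold (4.24 ± 1.21) and Il6 13.5-fold (3.75 ± 1.04). Also higher were Hdc (3.64 ± 0.59), the GTPase Gbp5 (3.24 ± 0.68), the siderophore-binding Lcn2 (3.19 ± 0.48), Marco (2.99 ± 0.43) and Ifi209 (2.85 ± 0.66). The mannose receptor Mrc1 fell 13.5-fold (-3.75 ± 0.71), and Fbp1 6.52-fold (-2.71 ± 0.68). Fcrls (-2.31 ± 0.49), Daglb (-2.19 ± 0.30), Btbd17 (-2.07 ± 0.37), Arhgap15 (-2.02 ± 0.33), the chemokine receptor Ccr2 (-2.00 ± 0.53) and Rgs18 (-1.99 ± 0.31) fell as well.

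Proinflammatory cytokines and chemokines rose in 10 of 22 cases (17 adjusted over the list alone, adjusted p = 1.19e-08, 0.650 with an estimated correlation). The cytokine subunit Ebi3 (1.33 ± 0.25), Il1a (2.90 ± 0.60) and Tnf (1.97 ± 0.54) were among them. Interferon-stimulated genes rose in 28 of 37 cases (37 adjusted over the list alone, adjusted p = 5.14e-18, 0.650 with an estimated correlation), with Bst2 (2.52 ± 0.40) and the ubiquitin-like Isg15 (3.75 ± 0.81). Ifnb1 itself, at least 2.49-fold higher, was called with some alternatives (adjusted p = 0.0598, 0.0288 with the replicate number as a block, 0.0223 without LPS replicate 2). Maturation genes had 10 of 30 up (15 adjusted over the list alone, adjusted p = 2.34e-08, 0.650 with an estimated correlation). They included Birc3 (1.15 ± 0.22), Socs2 (0.90 ± 0.18) and the costimulatory ligand Cd86 (1.53 ± 0.47, adjusted p = 0.0300). Feedback inhibitors had 11 of 23 up (14 up and 2 down adjusted over the list alone, adjusted p = 1.75e-05), including Cish (0.69 ± 0.13) and Il1rn (1.56 ± 0.30), and MHC class I presentation 5 of 18 (6 adjusted over the list alone, adjusted p = 0.00654). They had adjusted p = 0.722 and 0.785 with an estimated correlation.

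Oxidative phosphorylation had 8 of 35 members down (16 adjusted over the list alone, adjusted p = 4.21e-08, 0.495 with an estimated correlation), among them Atp5o of ATP synthase (-0.91 ± 0.15) and Ndufa5 of complex I (-0.75 ± 0.12). Cholesterol synthesis had 9 down and 1 up of 23 (12 and 1 adjusted over the list alone, adjusted p = 1.08e-05), with a fall of Hmgcs1 (-0.85 ± 0.19). Cell cycle genes had 2 of 32 down (11 adjusted over the list alone, adjusted p = 6.88e-08), with the replication clamp Pcna at -0.75 ± 0.19. These lists had adjusted p = 0.738 and 0.785 with an estimated correlation. Macrophage markers went both ways, 3 up and 5 down of 25 (4 and 5 adjusted over the list alone), and the list was not called (adjusted p = 0.257), with the lipid receptor Trem2 at -1.41 ± 0.24. Irf4 stood 0.73 ± 0.27 above unstimulated cells (adjusted p = 0.0713) with all 5 LPS arrays above the 5 unstimulated ones (exact two-sided permutation p = 0.00794), and was called with the replicate number as a block (adjusted p = 0.0237).

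In all 1384 genes were called, 812 up and 572 down, and 435 changed at least 2-fold. Of 32 named genes called, 29 had all 5 LPS arrays on the called side (by rule for the largest), and Il1a, Tnf and Isg15 had 4. The 8 list calls described, of 12 among 25 lists, had all 5. With the replicate number as a block 2753 genes were called. Without the later slide 2239 genes were called and the 32 kept the call, 7 with changes over 1.5 times as large, such as Isg15 (4.69), Cxcl10 (5.05, but 3.64 without LPS replicate 3) and Mrc1 (-4.43). A slide block called 4713 genes, 24 of the 32 kept the call and 6 lost it. Fcrls (0.36) and Mrc1 (0.23) turned positive, and the macrophage list was called upward (adjusted p = 0.0185). No slide held both groups. Cxcl10 and Tnf lost the call without LPS replicate 1 or 3, and Cd86 without any of 6 arrays (unstimulated replicates 1 to 3, LPS replicates 1, 4 and 5). Ccr2 and Cd86 were not called with Agilent's log ratios, Pcna and Tnf with Cy5 alone, Cd86 with probe means or Ccr2 with backgrounds as scanned. Median centring, which called 638 genes, ended the calls of Atp5o, Cish, Hmgcs1 and Pcna. The split moved to 682 up and 732 down with Agilent's log ratios and to 632 and 732 with Cy5 alone.

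In unstimulated cells Ch25h, which makes 25-hydroxycholesterol, was 19.3-fold higher in KO than in control cells (log2 difference 4.27, SE 0.48, adjusted p = 7.46e-07, n = 5 each). Spp1, which encodes osteopontin, was 14.3-fold higher (3.84 ± 0.55). Bex1 (3.47 ± 0.60), Fbxo32 (3.46 ± 0.35), Foxf2 (3.40 ± 0.39), Sgk1 (3.17 ± 0.58) and Inhba (3.12 ± 0.63) were also higher. The pyrimidine-degrading enzyme Upb1 was 28.3-fold lower (-4.82 ± 0.50). Also lower were the interferon-inducible Ifi27l2a (-3.70 ± 0.73), Septin4 (-3.60 ± 0.43), Ccr2 (-3.40 ± 0.53), Slc27a3 (-3.09 ± 0.25) and the GTPase Gimap5 (-3.07 ± 0.84).

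Of 30 measured maturation and migration genes 23 were lower in KO cells and 0 higher (25 lower adjusted over the list alone, adjusted p = 1.04e-13, 0.495 with an estimated correlation). They included the adhesion molecule Icam1 (-1.45 ± 0.19), the chemokine Ccl22 (-2.32 ± 0.37), the signalling adaptor Traf1 (-2.25 ± 0.38), the migration receptor Ccr7 (-1.79 ± 0.51) and the maturation markers Cd86 (-2.11 ± 0.47) and Cd83 (-1.56 ± 0.35). In MHC class II presentation 8 were lower and 2 higher of 19 (8 and 3 adjusted over the list alone, adjusted p = 0.0184, 0.785 with an estimated correlation). The class II transactivator Ciita (-1.93 ± 0.33), the peptide-loading chain H2-DMa (-1.09 ± 0.18), H2-Aa (-1.61 ± 0.28) and the invariant chain Cd74 (-1.77 ± 0.35) were lower. The tetraspanin Cd9 was higher (1.51 ± 0.26), and H2-Ab1 (-0.0357 ± 0.12) was not called (adjusted p = 0.883). Cholesterol synthesis had 16 of 23 members lower (19 adjusted over the list alone, adjusted p = 3.61e-12, 0.495 with an estimated correlation). Hsd17b7 (-1.11 ± 0.20) and Cyp51 (-1.73 ± 0.32) were among these. Oxidative phosphorylation had 5 of 35 lower (adjusted p = 0.000748), and glycolysis 6 of 21 (adjusted p = 0.00784), with Pfkp (-0.93 ± 0.15). Their adjusted p was 0.743 and 0.785 with an estimated correlation.

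Macrophage markers had 6 members higher and 1 lower of 25 (7 and 2 adjusted over the list alone, adjusted p = 0.00752, 0.785 with an estimated correlation). Marco (2.28 ± 0.43) and the chitinase-like Chil3 (0.85 ± 0.17) were higher. Neutrophil and granule markers had 2 of 16 lower (5 adjusted over the list alone, adjusted p = 0.0129, adjusted p = 0.738 with an estimated correlation), with the protease Mmp9 at -1.45 ± 0.23. Lysosomal genes had 4 of 30 higher (5 adjusted over the list alone, adjusted p = 0.00250), with the proton pump subunit Atp6v1a at 0.82 ± 0.16, and lipid efflux 6 of 20 (adjusted p = 0.0355). Both lists had adjusted p = 0.785 with an estimated correlation. The arginine and alternative activation list had 7 lower and 1 higher of 24 (10 and 2 adjusted over the list alone, adjusted p = 0.0386, adjusted p = 0.495 with an estimated correlation). Its lipoxygenase Alox15 was at least 3.96-fold lower. Dendritic cell identity genes went both ways, 2 higher and 4 lower of 23 (4 and 9 adjusted over the list alone, adjusted p = 0.362). Dpp4 was lower (-2.36 ± 0.41) and the receptor Clec9a at least 2.76-fold higher. The IRF list had 5 of 23 lower (adjusted p = 0.0954), with Irf5 at -1.81 ± 0.24. Immediate-early and heat shock genes had 3 higher and 1 lower of 19 (3 and 2 adjusted over the list alone, adjusted p = 0.317), with the stress-induced Ddit3 at 1.59 ± 0.23. Markers of other cell types were not called as lists. The adjusted p was 0.987 for plasmacytoid dendritic cells (2 members higher, 2 higher and 1 lower adjusted over the list alone, list median -0.0923 but mean 0.0792) and 0.824 for B cells. For T and NK cells it was 0.847 (0 of 7 members called by limma, 0 up and 0 down at an unadjusted p under 0.05). It was 0.0850 for mast cells, basophils and eosinophils, 0.112 for erythroid and megakaryocytic cells and 0.780 for stroma and endothelium (median -0.0343 but mean 0.12).

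In all 1584 genes were called, 781 higher and 803 lower in KO cells, and 575 differed at least 2-fold. All 39 named genes that were called had all 5 KO arrays on the called side of the control mean (by rule for the largest), as did 9 of the 10 list calls (lysosome 4 of 5). Blocking on the slide called 5697 genes, and 25 of the 39 named genes kept the call and 11 lost it. H2-DMa (0.13), Ciita (0.21) and Cd74 (0.97) turned positive. Of the 10 list calls 6 remained, and the maturation (adjusted p = 0.829) and arginine (0.546) calls ended. MHC class II (0.183) and glycolysis (0.240) changed direction, and the IRF list (0.0465, upward) and immediate-early list (0.00321) were called. The sign of H2-Aa (0.15) and Cd83 (0.0385) changed with Agilent's log ratios, which also ended the calls of Ccl22, Ccr2 and Ccr7. That of Chil3 changed with Cy5 alone (-0.14). Gimap5 lost its call without control replicate 4 and Ccr7 without KO replicate 1 or 5 (-1.15 without the latter), with array weights, or with only the compared arrays. The arginine call ended under 14 alternatives and without KO replicate 1. That of lipid efflux ended without the later slide, with the scan day as a block and without control replicate 4 or 5 or KO replicate 2, 3 or 4. Leaving out any 1 of these 5 arrays gave a call of the IRF list. The MHC class II call ended with Agilent's log ratios, the replicate number as a block, backgrounds as scanned and without control replicate 2 or 3. The macrophage call ended with Cy5 alone and the neutrophil call with backgrounds as scanned or a stricter signal filter. With median centring 346 genes were higher and 588 lower.

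**Figure D2:**
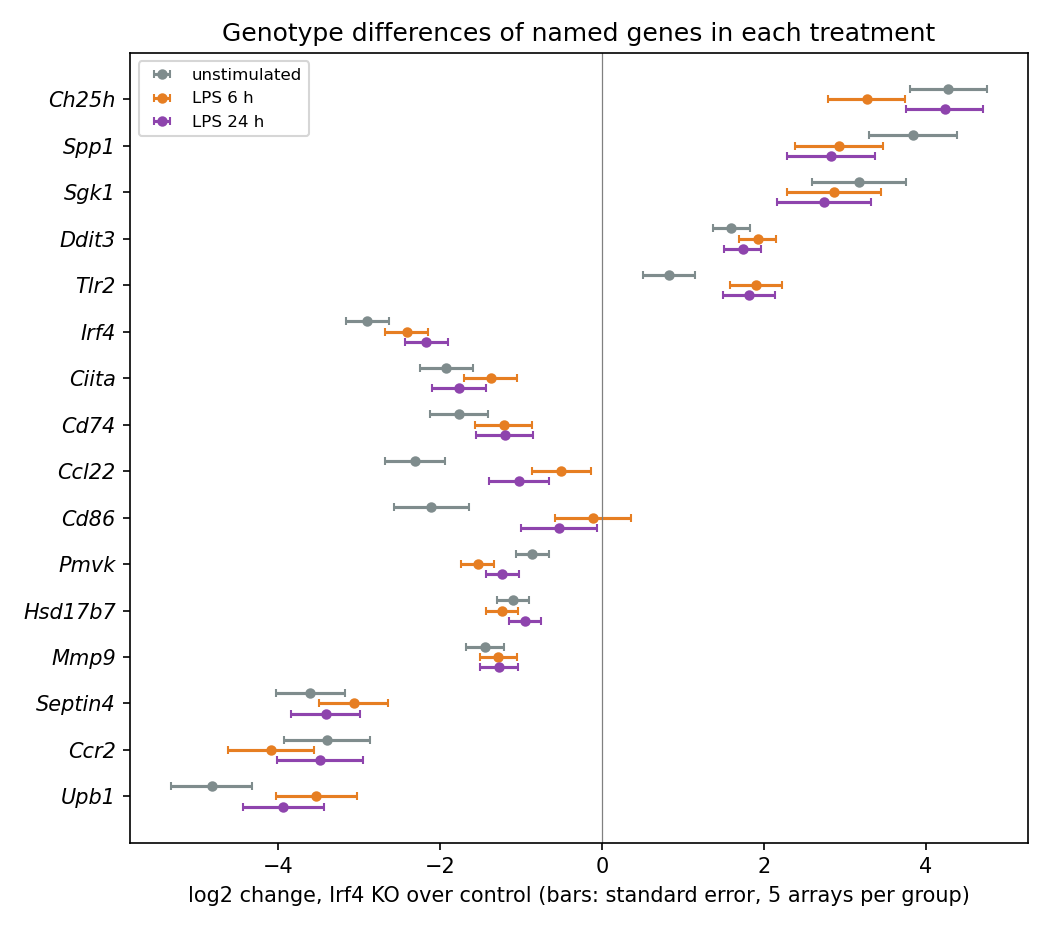
Log2 difference of KO from control cells (horizontal axis, ± SE) for named genes at 0, 6 and 24 h of LPS, n = 5 arrays per group. Ch25h was 4.27, 3.26 and 4.23 higher and Upb1 was -4.82, -3.53 and -3.94.

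At 6 h of LPS, Ch25h was 9.61-fold higher in KO than in control cells (log2 difference 3.26, SE 0.48, adjusted p = 3.67e-05, n = 5 each). The chemokines Cxcl1 (3.61 ± 0.88, adjusted p = 0.00645) and Cxcl2 (3.16 ± 0.81, adjusted p = 0.00952) were higher, but stood at 2.52 and 2.26 without the later slide, and neither was called with only the compared arrays or with the slide as a block. The ephrin receptor Epha4 (3.26 ± 0.48), Spp1 (2.93 ± 0.55) and Sgk1 (2.87 ± 0.58) were higher as well. Bex1, not well above background in control cells, was at least 9.0-fold higher. Ccr2 was 17.1-fold lower (-4.09 ± 0.53), with Upb1 (-3.53 ± 0.50), Septin4 (-3.07 ± 0.43), Rnase6 (-2.93 ± 0.47) and Mab21l3 (-2.61 ± 0.30).

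Proinflammatory cytokines and chemokines had 6 of 22 members higher (9 adjusted over the list alone, adjusted p = 2.42e-05, adjusted p = 0.785 with an estimated correlation). The growth factor Csf2 (2.66 ± 0.30) and the interleukin 12 subunit Il12a (2.24 ± 0.35) were higher, while Il6 (2.62 ± 1.04, adjusted p = 0.105) was not called, nor without the later slide (0.98, adjusted p = 0.0716). Interferon-stimulated genes were higher as a list (adjusted p = 5.59e-06, adjusted p = 0.785 with an estimated correlation) although no member of 37 was called by limma (12 up and 1 down at an unadjusted p under 0.05). Cxcl10 stood at 3.06 ± 1.21 (adjusted p = 0.103) and without the later slide at 1.39 (adjusted p = 0.233). The pattern recognition list had 6 of 25 higher (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.00145, adjusted p = 0.743 with an estimated correlation), including Tlr2 (1.90 ± 0.32) and Tlr4 (1.42 ± 0.25). Cholesterol synthesis had 17 of 23 lower (19 adjusted over the list alone, adjusted p = 1.94e-13), with Pmvk (-1.54 ± 0.21) and Hsd17b7 (-1.24 ± 0.20), and oxidative phosphorylation 8 of 35 (11 adjusted over the list alone, adjusted p = 2.38e-07), with Atp5o (-0.76 ± 0.15). They had adjusted p = 0.495 and 0.498 with an estimated correlation.

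Neutrophil and granule markers had 4 of 16 lower (adjusted p = 0.00204, adjusted p = 0.615 with an estimated correlation). Mmp9 was -1.28 ± 0.23 and the granule protein Ngp at least 2.56-fold lower. Macrophage markers had 4 higher and 1 lower of 25 (6 and 1 adjusted over the list alone, adjusted p = 0.00355), with Chil3 at 0.93 ± 0.17, and lysosomal genes 3 of 30 higher (adjusted p = 0.0119). They had adjusted p = 0.785 and 0.803 with an estimated correlation. The maturation list was not called (adjusted p = 0.308, 4 of 30 lower), with Socs2 lower (-0.79 ± 0.18) and Cd86 at -0.12 ± 0.47 (adjusted p = 0.917, -0.73 without the later slide). Neither was MHC class II (adjusted p = 0.183), of whose 19 members 6 were lower and 2 higher (8 and 2 adjusted over the list alone). H2-DMa (-1.27 ± 0.18), Ciita (-1.38 ± 0.33) and Cd74 (-1.22 ± 0.35) were lower. The cell cycle list was lower (adjusted p = 0.00427, adjusted p = 0.829 with an estimated correlation) with 1 member called (0 adjusted over the list alone). Ddit3 (1.92 ± 0.23) and Trib3 (1.77 ± 0.28) were higher.

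In all 1364 genes were called, 701 higher and 663 lower in KO cells, and 444 differed at least 2-fold. All 29 named genes that were called had all 5 KO arrays on the called side (by rule for the largest), as did 7 of the 9 list calls (lysosome and cell cycle 4 of 5). When the slide was a block 16 of the 29 kept the call and 9 lost it. Cxcl1 (-0.0721), Cxcl2 (-1.03), Tlr4 (-0.48) and Cd74 (0.49) changed sign (without the later slide Cxcl2 was then called lower, -2.48, adjusted p = 0.0306), and 7 of 9 list calls remained, without cell cycle and proinflammatory genes. Fitting the 10 compared arrays alone gave 726 genes. Cxcl2 was not called with Agilent's log ratios, Chil3 with Cy5 alone or Ciita with backgrounds as scanned. Cd74 lost its call without control replicate 1 or 2 or KO replicate 5. Without the later slide the cell cycle call ended (adjusted p = 0.299) and the maturation list was called lower (adjusted p = 0.000609). Without control replicate 3 the interferon-stimulated call ended too, and without control replicate 4 or 5 the lysosome call. Array weights ended the calls of interferon-stimulated, lysosome, macrophage and proinflammatory lists, and a stricter signal filter that of neutrophil markers. With median centring, which put the median of all genes at -0.11, 330 genes were higher and 477 lower.

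At 24 h of LPS, Ch25h was 18.7-fold higher in KO than in control cells (log2 difference 4.23, SE 0.48, adjusted p = 8.46e-07, n = 5 each). The collagenase Mmp13 (3.26 ± 0.90), Clec1b (3.15 ± 0.29), Ms4a7 (2.87 ± 0.38), the glutamate transporter Slc1a2 (2.83 ± 0.31) and Spp1 (2.83 ± 0.55) were also higher. Upb1 was 15.3-fold lower (-3.94 ± 0.50) and Plppr4 12.4-fold lower (-3.64 ± 0.40). Ccr2 (-3.49 ± 0.53), S100a9 (-3.43 ± 0.73), Septin4 (-3.41 ± 0.43) and Plet1 (-3.16 ± 0.58) were lower too.

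Maturation and migration genes were lower in 11 of 30 cases (14 adjusted over the list alone, adjusted p = 4.73e-06, adjusted p = 0.743 with an estimated correlation). Socs2 (-1.62 ± 0.18), Tmem123 (-1.55 ± 0.32) and Stat4 (-2.21 ± 0.47) were among them. Cholesterol synthesis had 7 of 23 lower (adjusted p = 0.000391), with Pmvk at -1.24 ± 0.21, and lysosomal genes 4 of 30 higher (5 adjusted over the list alone, adjusted p = 8.41e-05), with Atp6v0d2 at 1.32 ± 0.14. Both lists had adjusted p = 0.785 with an estimated correlation. Neutrophil and granule markers had 6 of 16 lower (7 adjusted over the list alone, adjusted p = 0.00351), Mmp9 (-1.27 ± 0.23) among them, and macrophage markers 5 higher and 2 lower of 25 (8 and 2 adjusted over the list alone, adjusted p = 0.0241), with Trem2 at 1.27 ± 0.24. With an estimated correlation these had adjusted p = 0.650 and 0.785. Interferon-stimulated genes were higher as a list (adjusted p = 0.000513, adjusted p = 0.829 with an estimated correlation) with none of 37 members called by limma (10 up and 0 down at an unadjusted p under 0.05). Proinflammatory genes had 4 higher and 1 lower of 22 (7 and 2 adjusted over the list alone, adjusted p = 0.0392, adjusted p = 0.829 with an estimated correlation), with Il12a at 1.96 ± 0.35. MHC class II was not called as a list (adjusted p = 0.625, 3 higher and 3 lower of 19, 3 and 4 adjusted over the list alone, median -0.20 but mean 0.0136). Ciita (-1.77 ± 0.33) and Cd74 (-1.21 ± 0.35) were lower. Mast cell, basophil and eosinophil markers had 3 of 8 lower (adjusted p = 0.0448, adjusted p = 0.743 with an estimated correlation), among them Siglecf (-2.61 ± 0.40). Tlr2 (1.81 ± 0.32), Ddit3 (1.73 ± 0.23), Trib3 (1.96 ± 0.28) and Lox (2.13 ± 0.39) were higher.

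In all 1731 genes were called, 782 higher and 949 lower, and 572 differed at least 2-fold. The 28 named genes called (by rule for the largest), and the 8 list calls, had all 5 KO arrays on the called side. Under a slide block 5068 genes were called, 10 of the 28 named genes kept the call and 14 lost it. Plet1 (0.72), Mmp9 (0.31), Siglecf (0.94) and Trib3 (-0.14) changed sign. Of the 8 list calls only maturation remained. The interferon-stimulated (adjusted p = 4.75e-08), macrophage (0.0324), lysosome (0.0448) and cholesterol (0.0214) lists were called in the other direction, and MHC class II was called lower (0.0134). Mmp13 lost its call without control replicate 2 (it was called at 2.40 without the later slide), Cd74 without control replicate 2, KO replicate 5 or the later slide, and Il12a with Agilent's log ratios. Without the later slide the macrophage (adjusted p = 0.0792), proinflammatory (0.172) and mast cell (0.0558) calls ended. The macrophage call also ended without control replicate 2, 4 or 5, the proinflammatory without control replicate 2 or KO replicate 3 or 4 and the mast cell call without control replicate 4 or KO replicate 1, 2 or 3. The interferon-stimulated call ended without control replicate 2, and the neutrophil call with a stricter signal filter. Without KO replicate 5 S100a9 was -4.02.

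A difference of responses asks whether LPS changed a gene differently in KO and control cells. At 6 h, Traf1 responded more in KO cells (difference of log2 responses 2.58, SE 0.54, adjusted p = 0.0197). So did the costimulatory ligand Icosl (2.53 ± 0.43), the interferon-inducible Gbp2 (2.42 ± 0.47) and Zbp1 (2.39 ± 0.49), the receptor Calcrl (2.34 ± 0.42) and Pde4b (2.33 ± 0.44). Slc1a2 (adjusted p = 0.000784) and Csf2 (adjusted p = 0.00242) were called higher too, without a size, since neither was well above background in unstimulated KO cells. The responses of the transporter Flvcr2 (-2.21 ± 0.39), Tcf7l2 (-2.04 ± 0.46), Dixdc1 (-1.81 ± 0.36), Cisd1 (-1.26 ± 0.22), Rassf3 (-1.24 ± 0.26) and the Wnt receptor Fzd4 (-1.06 ± 0.24) were lower in KO cells. Clec9a (adjusted p = 0.00280) and the adenylate cyclase Adcy3 (adjusted p = 0.0317) were called lower, but neither was well above background at 6 h in either genotype.

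Maturation genes responded more in KO cells (adjusted p = 8.33e-16), with 2 of 30 called (15 adjusted over the list alone) and Icam1 at 1.5 ± 0.27. Cd86, at 1.99 ± 0.66, was not (adjusted p = 0.266). The list's mean KO difference was -1.35 unstimulated, -0.188 at 6 h and -0.752 at 24 h, so KO cells did not end above control. Interferon-stimulated genes had 2 of 37 called (3 adjusted over the list alone, adjusted p = 1.94e-13), proinflammatory genes 1 of 22 (6 adjusted over the list alone, adjusted p = 7.66e-09) and MHC class I presentation 1 of 18 (6 adjusted over the list alone, adjusted p = 0.00102). The immunoproteasome subunit Psmb8 stood at 1.22 ± 0.27. Feedback inhibitors, with Nfkbie at 1.62 ± 0.30, had 1 of 23 called (4 adjusted over the list alone, adjusted p = 0.00655). By limma 0 members were called in 2 lists. Glycolysis responded more (2 of 21 adjusted over the list alone, 4 up and 0 down at an unadjusted p under 0.05, adjusted p = 0.00261) and lipid efflux less (0 of 20, 1 down at an unadjusted p under 0.05, adjusted p = 0.0392). Both lists had adjusted p = 0.785 with an estimated correlation. Neither Il6 (4.15 ± 1.47, adjusted p = 0.339) nor Irf4 (0.49 ± 0.38, adjusted p = 0.872) was called.

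The test called 49 genes, 33 with a higher and 16 with a lower response in KO cells, and 36 differed at least 2-fold. All 19 named genes called, and 6 of the 7 list calls (glycolysis 3 of 5), had all 5 KO LPS arrays on the called side of the control response. Without the later slide 143 genes were called, the 19 kept the call, Il6 was called (2.51, adjusted p = 0.00699), and the feedback (0.299) and lipid efflux (0.249) calls ended. The feedback call also ended without control LPS 6 h replicate 3, which alone gave 81 genes. With the slide as a block 2 of the 19 named genes and 1 of 7 list calls (proinflammatory) remained. The feedback and glycolysis lists changed direction, and 10 genes were higher and 25 lower. Leaving out 1 of 20 arrays ended the calls of Tcf7l2 (10 arrays), Rassf3 (5), Fzd4 (15), Adcy3 (10), Psmb8 (8) and lipid efflux (10), and without control LPS 6 h replicate 5 that of glycolysis. Of the 19, 12 kept the call with only the compared arrays and 6 in every alternative other than a slide block. Flvcr2 and Dixdc1 lost it with Agilent's log ratios, Cisd1 with median centring, Gbp2 and Zbp1 with Cy5 alone, and Dixdc1 and Icam1 with backgrounds as scanned. The split was 35 higher and 10 lower with Agilent's log ratios and 36 and 5 with median centring.

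At 24 h, the response of Mgarp was higher in KO cells (difference of log2 responses 2.45, SE 0.58, adjusted p = 0.0365). Slc1a2 was called without a size (adjusted p = 0.000678). Zbp1 (2.37 ± 0.49), Gbp2 (2.18 ± 0.47), Hdac9 (2.14 ± 0.48), the cytokine receptor Lifr (2.01 ± 0.34), the transferrin receptor Tfrc (1.97 ± 0.46) and the phosphatase Ptpn22 (1.83 ± 0.44) were higher too. Responses were lower in KO cells for Flvcr2 (-2.24 ± 0.39), Serinc5 (-1.94 ± 0.43), Tcf7l2 (-1.92 ± 0.46), Elmo1 (-1.71 ± 0.34), Glcci1 (-1.62 ± 0.34), Slc39a8 (-1.60 ± 0.35), Nlk (-1.47 ± 0.26) and Pcyt1a (-1.31 ± 0.18).

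All 9 list calls were upward. Interferon-stimulated genes had 2 of 37 members called (adjusted p = 1.19e-08) and MHC class I presentation 1 of 18 (4 adjusted over the list alone, adjusted p = 0.00102), with Psmb8 at 1.15 ± 0.27. Erythroid and megakaryocyte markers had 1 of 8, which was Tfrc (3 adjusted over the list alone, adjusted p = 0.0157). No member was called by limma in 6 lists, given with the number adjusted over the list alone and the number up at an unadjusted p under 0.05. These were maturation (1 and 8 of 30, adjusted p = 0.00246), proinflammatory genes (1 and 3 of 22, adjusted p = 0.00351) and MHC class II (0 and 4 of 19, adjusted p = 0.0271). Each had adjusted p = 0.785 with an estimated correlation. The other 3 were glycolysis (3 and 6 of 21, adjusted p = 0.000212), oxidative phosphorylation (2 and 8 of 35, adjusted p = 0.000259) and cholesterol synthesis (1 and 8 of 23, adjusted p = 0.000188). Their adjusted p was 0.785, 0.725 and 0.785 with an estimated correlation. Ndufa5 stood at 0.67 ± 0.18. Il6 was 2.82 ± 1.47 (adjusted p = 0.486) and called without the later slide (2.06, adjusted p = 0.0275).

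The test called 99 genes, 48 with a higher and 51 with a lower response in KO cells, and 60 differed at least 2-fold. All 17 named genes called, and the 9 list calls, had all 5 KO LPS arrays on the called side of the control response. Without the later slide 201 genes were called, 15 of the 17 kept the call (Mgarp and Tcf7l2 lost it) and the MHC class II call ended (adjusted p = 0.0530). A block for the slide called 6028 genes, and 11 of the 17 kept the call. Zbp1 (-0.0746), Gbp2 (-0.29), Hdac9 (-1.91), Slc39a8 (1.86) and Psmb8 (-0.87) changed sign. Only the oxidative phosphorylation and cholesterol calls remained of the 9 (MHC class I, MHC class II, interferon-stimulated, maturation and glycolysis lists turned downward). Median centring left 20 (15 higher, 5 lower) and 7 of the 17, and Agilent's log ratios gave 71 higher and 46 lower. In every alternative other than a slide block 2 of the 17 (Slc1a2 and Pcyt1a) kept the call. Leaving out unstimulated control replicate 1, 4 or 5 gave 65, 62 or 56 genes, KO unstimulated replicate 1 gave 50 and KO LPS 24 h replicate 3 gave 54. Leaving out an array ended the calls of Mgarp (12 of 20 arrays), Hdac9 (5), Tfrc (13), Ptpn22 (16), Tcf7l2 (14) and Psmb8 (11). Gbp2, Serinc5 and Slc39a8 lost theirs without KO unstimulated replicate 1, Serinc5 also without unstimulated control replicate 4 or 5 and Slc39a8 without KO LPS 24 h replicate 3. The MHC class II call ended without unstimulated control replicate 2 or 3, control LPS 24 h replicate 4 or 5 or KO unstimulated replicate 1 or 5, and the proinflammatory call without control LPS 24 h replicate 2.

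Within KO cells at 6 h of LPS Cxcl10, not well above background in unstimulated KO cells, rose at least 1367-fold (adjusted p = 6.35e-07). Il6 rose by 8.32 ± 1.04, Tnf by 4.04 ± 0.54, Cd86 by 3.22 ± 0.47 and Irf4 by 1.38 ± 0.27 (log2 ± SE, adjusted p from 1.67e-06 to 0.000318, all 5 arrays on the side called). At 24 h Cxcl10 was called again (adjusted p = 0.000412) and the others rose by 6.57 ± 1.04, 3.1 ± 0.54, 3.11 ± 0.47 and 1.46 ± 0.27. At 6 h 22 of 22 proinflammatory (adjusted p = 1.51e-19), 37 of 37 interferon-stimulated (adjusted p = 4.22e-30) and 22 of 30 maturation genes (23 adjusted over the list alone, adjusted p = 5.81e-13) rose. At 24 h these were 15 (18 adjusted over the list alone, adjusted p = 8.30e-13), 36 (adjusted p = 2.09e-29) and 22 genes (24 adjusted over the list alone, adjusted p = 1.94e-13). Between 6 and 24 h proinflammatory genes fell, with 6 of 22 called in KO (9 adjusted over the list alone, adjusted p = 2.01e-07) and 4 in control cells (5 adjusted over the list alone, adjusted p = 0.00204). With an estimated correlation the adjusted p was 0.495 each at 6 h, 0.498, 0.495 and 0.495 at 24 h, and 0.722 and 0.785 between them. The difference between genotypes was not tested. The calls numbered 2996 (1603 up, 1393 down) at 6 h and 2043 (1159 up, 884 down) at 24 h in KO cells. Between 6 and 24 h they numbered 872 (399 up, 473 down) in KO and 618 (371 up, 247 down) in control cells.

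With the slide as a block these 4 counts were 893 (637 up, 256 down), 6228, 5838 and 1044. Cxcl10 in KO cells at 24 h then stood at -0.78, and the Irf4 calls in KO cells at 6 and 24 h ended (adjusted p = 0.225 and 0.373). The proinflammatory call in control cells ended without control LPS 24 h replicate 2. With the replicate number as a block 4778 genes were called in KO cells at 6 h and 2020 at 24 against 6 h. On the slide with both KO groups 2994 of the 2996 genes (99.9%) had the direction called at 6 h. Its arrays (LPS replicate 1, unstimulated 3 to 5) also made the calls and share no replicate number. Likewise, control cells at 24 against 6 h had 587 of 617 genes in the direction called on 1 slide and 556 of 618 on the later slide. Leaving out KO LPS 6 h replicate 2 or 3 gave 563 or 492 genes in KO cells at 24 against 6 h, and control LPS 6 h replicates 1, 2 or 3 gave 322, 338 or 1224 in control cells. The KO split at 6 h was 1387 up and 1901 down with Agilent's log ratios and 1237 and 2122 with Cy5 alone, and at 24 h 745 and 351 with median centring and 1034 and 1328 with Cy5 alone.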

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

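The tests of a wrong label or failed stimulation, of a swap, and all tests on the replicate numbers were chosen after the result was seen, and the others before. The alternatives without the 2 later arrays and with a term for the replicate numbers were also chosen after it.

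An array was set apart when its gap to the nearest array of its group exceeded Dixon's limit for 5 values, which chance passes in about 1 of 20 groups. Of 168 tests on sample values 16 passed it. On the first principal component, control LPS 6 h replicate 3 stood at -43.8 (others 19.2 to 39.8) and control LPS 24 h replicate 2 at -33.1 (others 7.23 to 22.9). The list means of the first were also apart for proinflammatory genes (0.526, others 3.30 to 3.82), interferon-stimulated genes (-0.0804, others 3.22 to 4.35), maturation (1.60, others 3.15 to 3.39) and cholesterol synthesis (0.633, others -0.467 to -0.168). Those of the second were apart for proinflammatory genes (0.377, others 2.49 to 2.86) and cell cycle (-1.5, others -2.50 to -2.40). Control unstimulated replicate 5 had 27230 probes well above background (others 22183 to 22851), a dendritic cell identity mean of 1.43 (others 1.58 to 1.63) and an erythroid and megakaryocyte mean of 0.547 (others 0.683 to 0.731). KO LPS 24 h replicate 5 had 20628 probes well above background (others 21503 to 21762), and KO LPS 24 h replicate 3 a proinflammatory mean of 3.30 (others 2.96 to 3.05). The feedback inhibitor mean of KO unstimulated replicate 5 was 0.904 (others 0.717 to 0.763), the plasmacytoid mean of KO LPS 6 h replicate 4 was 0.440 (others 0.282 to 0.307) and the B cell mean of KO LPS 6 h replicate 5 was -0.387 (others -0.289 to -0.250). Among named genes 91 of 822 group tests passed the limit, 43 of them in control LPS 6 h replicate 3 and 21 in control LPS 24 h replicate 2.

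These 2 arrays, labelled as LPS-treated control cells, lay with the unstimulated control arrays. A fault of the later slide should reach genes that LPS leaves alone. Such genes deviated by 0.451 and 0.534, at most 0.337 times as much as LPS genes. A missing response lowers this ratio too, so a lesser fault stays open. A swap within the series needs an unstimulated array with an LPS response, while the highest slope among the 10 was 0.101. Cells that had not responded to LPS, through a wrong label or a failed stimulation, remain a candidate explanation, since the higher slope of the 2 arrays on the KO response was 0.105. Their Irf4 log2 ratios of 2.13 and 2.68 lay above those of the unstimulated control arrays (1.16 to 1.79), which goes against cells that had seen no LPS at all. No biological explanation was tested, and the array labels were kept as given.

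The means of replicates 4 and 5 and of 1 to 3 differed in 1 direction in all 6 groups for 54.8% of genes (chance 3.13%). In unstimulated KO cells, however, only replicate 5 stood apart on the first component within the group (30.3, replicate 4 -3.57, replicates 1 to 3 -15.3 to -0.199). Replicate 1 also differed from replicates 2 to 4 there (SD of differences 0.461 to 0.507, against 0.186 to 0.203 among these). A term for replicates 4 and 5 therefore describes that group poorly. S100a8 (mean log2 difference 2.41) and S100a9 (1.5), abundant neutrophil transcripts, were higher in replicates 4 and 5. Most of the neutrophil list was too (Stfa2l1 2.84, Fpr1 0.63), but not Mmp8 (-0.24) or Padi4 (-0.26). On the slide with KO LPS 6 h replicates 2 to 5, arrays from the 2 sides differed at least 2.00 times as much as arrays of 1 side, so the slide or scan day does not account for it there. A lower share of dendritic cells would raise the markers of all other types alike, but the macrophage list's median difference was -0.550 on average over the groups (SD 0.25). Neutrophils among the selected cells could contribute and stay open, since the neutrophil list's median was above 0.5 in 2 of 6 groups, although selection on CD11c should remove most of them. A shared day or litter behind the replicate number is another open explanation, and neither it nor a biological difference was tested.

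LPS at 6 h called 2996 genes in KO and 1314 in control cells. Without the 2 later arrays the ratio of the counts fell from 2.28 to 1.25, so these arrays may account for much of it. With the slide as a block the ratio was 0.231, but the blocks join groups of different size and the slide effect cannot be told apart from the design. A larger response of KO cells is also consistent with the data, because without the 2 arrays the KO response had a slope of 1.15 on the control response over 4346 genes (1.13 to 1.17 when genes were resampled, r = 0.908 across genes, which are not independent replicates).

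The differences of responses between genotypes were set apart by their own test, with 49 genes at 6 h and 99 at 24 h. At 6 h the differences of log2 responses were Slc1a2 2.98, Csf2 2.66, Traf1 2.58, Icosl 2.53, Gbp2 2.42, Zbp1 2.39 and Calcrl 2.34. Others were Pde4b 2.33, Icam1 1.5, Nfkbie 1.62 and Psmb8 1.22. Below 0 were Flvcr2 -2.21, Tcf7l2 -2.04, Dixdc1 -1.81, Clec9a -1.35, Cisd1 -1.26, Rassf3 -1.24, Fzd4 -1.06 and Adcy3 -1.02. At 24 h they were Slc1a2 3.05, Mgarp 2.45, Zbp1 2.37, Gbp2 2.18, Hdac9 2.14, Lifr 2.01, Tfrc 1.97, Ptpn22 1.83 and Psmb8 1.15. Those below 0 at 24 h were Flvcr2 -2.24, Serinc5 -1.94, Tcf7l2 -1.92, Elmo1 -1.71, Glcci1 -1.62, Slc39a8 -1.60, Nlk -1.47 and Pcyt1a -1.31. Slc1a2, Csf2, Adcy3 and Clec9a were not well above background on any array of at least 1 of the compared groups, so their values are not measured sizes. With an estimated correlation none of the list calls that follow held (adjusted p = 0.495 to 0.785). Blocking on the slide left 1 of 7 at 6 h and 2 of 9 at 24 h, and at 24 h the interferon-stimulated (adjusted p = 4.08e-08), MHC class I (0.00755) and MHC class II (0.0420) lists were called in the other direction. List adjusted p at 6 h was maturation 8.33e-16, interferon-stimulated 1.94e-13, proinflammatory 7.66e-09, MHC class I 0.00102, feedback 0.00655, glycolysis 0.00261 and lipid efflux 0.0392. At 24 h it was interferon-stimulated 1.19e-08, MHC class I 0.00102, maturation 0.00246, proinflammatory 0.00351 and MHC class II 0.0271. Others were glycolysis 0.000212, oxidative phosphorylation 0.000259, cholesterol synthesis 0.000188 and erythroid 0.0157.

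Each count was set against 100 drawn regroupings of the compared arrays into groups of 5, the real one included. This ignores slides and replicate numbers, whose effects could pass it, so chance cannot be excluded. It is unadjusted over comparisons. At most 2 regroupings called as many genes for KO against control in unstimulated cells (1584, highest other 808, 1 as large). The same held at 6 h (1364, 2071, 2) and 24 h (1731, 2920, 2) and for control LPS at 24 h (1384, 1827, 2). It held for LPS in KO cells at 6 h (2996, 472, 1) and 24 h (2043, 58, 1). From 5 to 9 did so for LPS in control cells at 6 h (1314, 2925, 8). This held for 24 against 6 h in control (618, 1894, 9) and KO cells (872, 2737, 6). It held for the differences of responses at 6 h (49, 1318, 8) and 24 h (99, 1966, 5). Splits that call many genes point to a structure of the samples. The highest other split for LPS in control cells at 6 h exchanged unstimulated replicate 5 with LPS replicate 3, 1 of the 2 later arrays, and 2880 genes were called without these. The highest other split put replicates 4 and 5 of both groups on 1 side for LPS at 24 h in control cells, KO against control at 6 and 24 h, and both 24 against 6 h comparisons. With a term for replicates 1 to 3 against 4 and 5, these counts were 2858, 2798, 3117, 1667 (control) and 2157 (KO). Among the 16 splits that part every pair of equal numbers, 1 was as large for LPS at 24 h in control cells (1384, highest other 272), for LPS at 6 h in KO cells (2996, highest other 162) and for 24 against 6 h in KO cells (872, highest other 1), and the higher ones kept pairs together.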

How the results depend on the processing

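The alternatives without the later slide, with local backgrounds as scanned, over unnamed features, with scan day as a block, with the slide as a random block, with a term for replicates 1 to 3 against 4 and 5, and the combinations of these were chosen after the data were seen. Of 7738 comparisons of a named gene's result with an alternative (227 results), 7106 kept the direction and the side of the threshold, 496 lost the call, 84 gained it and 52 changed direction with a call on either side. For 83 list results these numbers were 2573, 297, 22 and 49 of 2941. The mean Irf4 log2 ratios of the groups moved by less than 1 SD with the deposited table, and no other Irf4 probe could be tried. Genes near the background have the least certain log ratios.

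Counts of called genes moved by over 1.5 times under several alternatives, and the cause was not tested unless given. They are listed in this order: LPS at 6 and 24 h in control cells, at 6 and 24 h in KO cells, 24 against 6 h in control and KO cells, KO against control in unstimulated cells, at 6 and at 24 h, and the difference of responses at 6 and 24 h. Median centring called 661, 638, 1882, 1096, 208, 374, 934, 807, 998, 41 and 20 genes. Array weights, whose fit did not converge, called 6218, 4126, 6839, 6116, 5886, 5773, 3102, 6768, 5265, 1566 and 1569. Over all features, where more were tested, 2318, 2415, 5493, 3568, 1060, 1585, 3032, 2419, 3013, 83 and 187 were called. A term for replicates 1 to 3 against 4 and 5 gave 2603, 2858, 4884, 3822, 1667, 2157, 3439, 2798, 3117, 174 and 615, and leaving out the 2 later arrays as well gave 4755, 4165, 5690, 4905, 2618, 3242, 4440, 3237, 3332, 500 and 1123. The slide as a block gave 3873, 4713, 893, 6228, 1044, 5838, 5697, 1204, 5068, 35 and 6028, without the 2 later arrays 4241, 5243, 1105, 6834, 1629, 6620, 6481, 4137, 5886, 68 and 6631, and with the replicate term 2576, 2228, 1401, 129, 1029, 18, 226, 11, 548, 93 and 179. The replicate block over all groups gave 2483, 2753, 4778, 3725, 1571, 2020, 3336, 2727, 3042, 154 and 510. Within genotype the replicate block, which leaves out KO against control, gave 2559, 2835, 4826, 3805, 1639, 2104, 214 and 597. In the 3 comparisons whose numbers pair the arrays it changed no other call of a gene or list named. In the other 8 pairing stays open, and for control LPS 6 h and KO against control at 6 and 24 h only the pair with a later array was under 0.1. Best correlated with an array of their own number were 13 of 30 arrays.

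Without the 2 later arrays LPS in control cells called 2880 genes at 6 h and 2239 at 24 h. Comparing 24 with 6 h called 1071 in control and 1488 in KO cells. The response difference called 143 at 6 h and 201 at 24 h. With scan day as a block these were 2560, 2469, 982, 1327, 103 and 192. Only the compared arrays, with fewer degrees of freedom, gave 726 and 1137 for KO against control at 6 and 24 h. In control cells they gave 75 each for LPS at 6 h and 24 against 6 h. The difference of responses at 24 h had 213 genes with Cy5 alone, 63 with a signal filter over all 30 arrays and 35 with the slide as a random block (correlation 0.103), which called 474 for 24 against 6 h in KO cells, and that at 6 h had 28 with backgrounds as scanned. Leaving out 1 array gave, in the order above, 744 to 2599, 953 to 1759, 2522 to 2916, 1543 to 1939, 322 to 1224, 492 to 927, 1104 to 1560, 978 to 1456, 1269 to 1835, 35 to 81 and 50 to 108 genes.

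Under the slide block, log2 values with a changed sign are given with all arrays and then without the 2 later ones. They were Fcrls 0.36 and 0.76, Mrc1 0.23 and 0.43, Trem2 0.27 without these for LPS at 24 h in control cells, Cxcl10 -0.78 and -0.20 for LPS at 24 h in KO cells. They were also H2-DMa 0.13 and 0.49, Ciita 0.21 with all arrays, Cd74 0.97 and 1.28 for KO against control at 0 h, Cxcl1 -0.0721 and -1.43, Cxcl2 -1.03 and -2.48, Tlr4 -0.48 and -0.14, Cd74 0.49 and 0.80 for KO against control at 6 h. They were also Plet1 0.72 and 1.01, Mmp9 0.31 and 0.0815, Siglecf 0.94 and 0.95, Trib3 -0.14 and -0.60, S100a9 0.42 without these, Trem2 -0.40 without these for KO against control at 24 h, Zbp1 -0.0746 and -0.0737, Gbp2 -0.29 with all arrays, Hdac9 -1.91 and -3.11, Slc39a8 1.86 and 2.66, Psmb8 -0.87 and -0.70 for the response difference at 24 h. Lists that changed direction had these adjusted p values in the same order: macrophage 0.0185 and 0.00251, neutrophil 0.683 and 0.252, lysosome 0.0860 and 0.000271 for LPS at 24 h in control cells, cell cycle 0.143 and 0.249 for 24 against 6 h in KO cells. Others were MHC class II 0.183 and 0.0496, IRF family 0.0465 with all arrays, glycolysis 0.240 and 0.0278 for KO against control at 0 h, interferon-stimulated genes 4.75e-08 and 1.62e-06, macrophage 0.0324 and 0.00812, neutrophil 0.424 and 0.173, mast cell 0.480 and 0.185, cholesterol synthesis 0.0214 and 0.105, lysosome 0.0448 and 0.000427 for KO against control at 24 h. Others were feedback inhibitors 0.154 and 0.173, glycolysis 0.893 and 0.895 for the response difference at 6 h, MHC class II 0.0420 and 0.0101, MHC class I 0.00755 and 0.00853, interferon-stimulated genes 4.08e-08 and 2.32e-06, maturation 0.0851 and 0.660, glycolysis 0.0631 and 0.00465 for the response difference at 24 h. With the slide block and the replicate term the values were Fbp1 0.33 for LPS at 24 h in control cells, H2-DMa 0.28, Ciita 1.69, Dpp4 1.81 and H2-Aa 0.84 for KO against control at 0 h, Cxcl1 -0.64, Ciita 0.95 and Batf3 0.22 for KO against control at 6 h, Mmp13 -0.51 for KO against control at 24 h, Slc39a8 0.70 and Nlk 0.0123 for the response difference at 24 h. The list values were maturation 0.455 for LPS at 24 h in KO cells, MHC class II 0.0597, maturation 0.482 and dendritic cell identity 0.0205 for KO against control at 0 h, cell cycle 0.00414 and lysosome 0.929 for KO against control at 6 h, interferon-stimulated genes 0.00926 and cholesterol synthesis 0.321 for KO against control at 24 h, feedback inhibitors 0.408 for the response difference at 6 h, MHC class II 0.00637, MHC class I 0.245, interferon-stimulated genes 0.00225, maturation 7.07e-05 and erythroid 0.953 for the response difference at 24 h. H2-Aa (0.15) and Cd83 (0.0385) changed sign with Agilent's log ratios and Chil3 (-0.14) with Cy5 alone, all in unstimulated KO cells, Irf8 (-0.26) at 6 h with array weights, and the neutrophil list in control cells at 24 h with the filter over all arrays (adjusted p = 1.00).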

Other observations

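Which results to describe here was chosen after the data were seen, from genes and lists fixed earlier.

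Of 3 genes known from conventional dendritic cells, limma called Batf3 at 6 h between genotypes, and alternatives called more. Itgax, which encodes the CD11c chain used for the bead selection, was 0.40 ± 0.16, 0.33 ± 0.16 and 0.22 ± 0.16 in KO relative to control cells at 0, 6 and 24 h of LPS (log2 difference ± SE, adjusted p = 0.102, 0.20 and 0.428). Irf8, a relative of Irf4, was 0.24 ± 0.28, 0.0346 ± 0.28 and -0.41 ± 0.28 (adjusted p = 0.612, 0.960 and 0.366). Batf3, a partner of IRF factors, was called lower at 6 h (-1.04 ± 0.28, adjusted p = 0.0137) and stood at -0.66 ± 0.28 (adjusted p = 0.117) and -0.73 ± 0.28 (adjusted p = 0.0798) at the other times. The call at 6 h ended without KO replicate 2 or 3 (-0.87 and -0.86, adjusted p = 0.0548 and 0.0567), with only the compared arrays (-1.04, adjusted p = 0.131) and with the slide as a block (-2.12, adjusted p = 0.0762), and with that block and the term for replicates 4 and 5 the difference turned (0.22). Batf3 was called lower in unstimulated cells and at 24 h with the replicate number as a block, Cy5 alone, array weights or the term for replicates 4 and 5 (adjusted p = 1.22e-07 to 0.0197). The same held in unstimulated cells with only the compared arrays (adjusted p = 0.00378) and at 24 h without KO replicate 4 or 5 (0.0301 and 0.0432). Itgax was called higher in unstimulated KO cells under 9 alternatives (adjusted p = 0.00391 to 0.0484), among them the slide as a block (0.86). With that block Irf8 was called higher (1.73) in unstimulated KO cells and lower (-2.19) at 24 h, where it was also called with only the compared arrays (adjusted p = 0.0464).

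Across the 3 treatments, which share no arrays, 243 genes were lower and 239 higher in KO cells each time, against 3.99 and 3.38 for independent lists, but arrays of 1 replicate number deviated together (correlation 0.792 to 0.875 for KO cells at 6 and 24 h).

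In control cells at 24 h of LPS 4 further lists were called. Pattern recognition rose with 6 members up and 1 down of 25 (adjusted p = 0.0123), the IRF family with 3 of 23 up (8 adjusted over the list alone, adjusted p = 0.00937) and neutrophil and granule markers with 4 of 16 up (adjusted p = 0.0392), each with adjusted p = 0.785 with an estimated correlation. Lysosomal genes fell, with 5 of 30 called (adjusted p = 0.0103, adjusted p = 0.803 with an estimated correlation). With the slide as a block the neutrophil (adjusted p = 0.683) and lysosome (adjusted p = 0.0860) lists turned. Both calls also ended without the later slide (adjusted p = 0.289 and 0.237), with scan day as a block, with array weights and without unstimulated replicate 2 or 3 or LPS replicate 2 or 4. The first 2 calls ended without unstimulated replicate 5, pattern recognition also without LPS replicate 3 and IRF without LPS replicate 2 (adjusted p = 0.0583 to 0.0734).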
